A study of Rattus norvegicus with 23 samples.

How the data were processed

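Small RNA from rat PC12 cells was sequenced with an Illumina small RNA protocol after a miRNA-enriched fraction had been purified, per the labels' protocols. The cells had been transfected with a vector expressing Flag-tagged α1ACT with 11 glutamine repeats or with the empty vector, and stable clones had been selected with G418, per the labels' protocols. Groups were taken from the sample titles: 2 lines at 6 h, 24 h, 3 d and 10 d after splitting, with 2 libraries of the vector line at 6 h and 3 in each other group, 23 in all.

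Both tables hold whole-number read counts per mature miRNA entry, as the authors deposited them, with no normalization. The names the authors gave to the deposited tables point to sRNAbench with single assignment of each read (413 entries) and to Chimira (627 entries). The edgeR package was named as a tool, per the submitters' processing notes. The versions of these tools, the aligner, the miRBase release and the genome build are not given in the sources used here. Columns named control were matched to the vector line and columns named WT to the α1ACT line, an assumption that rests on the construct carrying the repeat of normal length. Each table has 12 further columns that belong to none of the 23 samples, and they were not used. The sRNAbench table has 1 entry with no name, which holds 0 counts and so 0% of the total, and it was left out.

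The choice of tables, the comparisons, the tests, the naming rule, the 23 lists and a set of alternatives were fixed before the data were examined. By the rule, the sRNAbench table was the main one if it could be mapped to all libraries that the Chimira table could. Both could be mapped to all 23, so the Chimira table was an alternative. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Entries were kept by filterByExpr (269 of 413 in the sRNAbench table, 305 of 627 in the Chimira table), scaled by trimmed mean of M values (TMM), and fitted with 1 mean per group over all 23 libraries with robust quasi-likelihood dispersions. The common biological coefficient of variation was 16.1%. Contrasts were the α1ACT line against the vector line at each time and as the mean of the 4 times, 10 d against 6 h in each line, the 3-degree-of-freedom F tests of time within each line, and the interaction of line and time. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. Standard errors come from the fitted log2 fold change and its F value, and CPM values are counts per total, TMM-scaled.

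Named miRNAs followed a rule. For the mean comparison, among miRNAs with a mean CPM of at least 10 that were called with 1 sign at all 4 times, the 8 with the largest log2 fold change in each direction were named, plus the 3 most abundant called. For each other contrast the 5 largest called in each direction with a mean CPM of at least 10 were named, and for the interaction the 5 smallest p. Of each list up to 4 members with the smallest p and examples of no call were named, as were the 10 most abundant miRNAs. Outside this rule, miR-92a-3p, miR-423-3p and miR-23b-5p were named after their values were seen. The lists were gene families, clusters and cell-type markers, matched on the hairpin name, and 17 of the 23 had 3 or more tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry.

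Depth per library ran from 448557 to 5070120 counts in the sRNAbench table. PCR reads carry no molecular identifiers, so counts are not independent molecules. Replicates were checked for duplicate libraries, and none was found: over replicate pairs the chi-square per degree of freedom of the counts lay between 22.4 and 224. For each library the counts of 154 miRNAs with at least 100 counts were compared between the tables, and 21 of 23 libraries matched their own name. The columns named vector 6 h replicate 2 and vector 10 d replicate 2 matched each other instead. The names of the sRNAbench table were kept, and the exchange was run as an alternative.

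Hairpin gene names, host genes and neighbours within 10 kb came from a gene table of assembly GRCr8, used for names and neighbourhood alone, since the build of the counts is not given in the sources used here. All 269 tested miRNAs matched a hairpin gene in it. Strand was not considered in naming a host gene or in finding neighbours.

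The alternatives were the other table, 3 other scalings, 2 other low-count filters, DESeq2 1.42.0, limma-voom, a replicate block, a fit of the 2 groups compared alone, leaving out each library, and, for lists, the other set tests and the more abundant arm alone. Chosen after seeing the data were the exchange of the pair of columns in each table, leaving out both libraries, leaving out the shallow vector library of 3 d with them, summing let-7a-1-3p and let-7c-2-3p, and a pair of scalings for the lists.

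The steps were tested on simulated data drawn from the means and library sizes of the 269 miRNAs, in 10 runs. In the mean comparison 47.0% of miRNAs changed by 1.2-fold were called, 88.6% of those changed by 1.5-fold and 99.3% of those changed by 2-fold, with 0.764% of unchanged ones. For the lines at 10 d these shares were 5.11%, 51.8%, 82.5% and 0.45%, and for 10 d against 6 h in the α1ACT line they were 9.63%, 50.4%, 71.9% and 0.314%. In the mean comparison a list raised by 1.5-fold was called in 10 of 10 runs with either correlation, and 0 of 160 other lists were. The simulated miRNAs were drawn independently of each other, while in the data the estimated correlation was 0.188 for the miR-30 family. The list runs therefore say nothing about false calls of lists with correlated members. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.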

Results

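Small RNA was sequenced from rat PC12 cells, a pheochromocytoma line that is widely used as a model of neuroendocrine and neuron-like cells. One line stably expressed α1ACT, a transcription factor made from the calcium channel gene CACNA1A, and the other carried the empty vector. Both lines were sampled at 6 h, 24 h, 3 d and 10 d after splitting, which gave 23 libraries in 8 groups (vector at 6 h, n = 2; each other group, n = 3). Total miRNA counts ran from 448557 (vector, 3 d, replicate 1) to 5070120 (α1ACT, 10 d, replicate 1). Both lines were dominated by a few miRNAs: the 10 most abundant entries took between 68.1% and 73.9% of the counts of a library. Over all libraries miR-375-3p, a miRNA of endocrine cells, led with 14.7% of counts, followed by miR-27b-3p (13.3%), miR-10b-5p (11.1%), let-7f-5p (8.69%), miR-30a-5p (6.59%), miR-22-3p (6.17%), miR-182 (3.13%), let-7i-5p (3.01%), miR-26a-5p (2.59%) and miR-16-5p (2.43%). Of 413 entries, 269 had enough counts to be tested. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. They do not give the number of stable clones behind each line, so a difference between the lines includes any difference between clones. The level of α1ACT itself was not measured in these small RNA libraries.

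The question of the series was which miRNAs α1ACT regulates, and the main comparison set the α1ACT line against the vector line as the mean of the 4 times. The α1ACT line had more miR-181a-5p, at 32.5 ± 11.1 CPM (counts scaled to library totals with TMM factors; SD, n = 12) against 8.48 ± 2.82 (n = 11), a fitted fold of 3.76. Both arms of miR-708, whose hairpin lies within the gene Tenm4, were higher too. Here miR-708-3p stood at 18.8 ± 4.77 CPM against 8.24 ± 4.02, and miR-708-5p at 13.8 ± 5.00 against 6.02 ± 2.88. The neural miRNA miR-9a-5p was at 41.7 ± 7.08 CPM against 26.0 ± 5.53, and the p53 target miR-34c-5p at 71.6 ± 10.0 against 53.6 ± 10.8. In the other direction, miR-143-3p, a miRNA abundant in smooth muscle and other mesenchymal cells, was at 493 ± 139 CPM in the α1ACT line against 849 ± 299 CPM. Also lower was miR-10a-5p, encoded in a Hox gene cluster, at 6978 ± 1098 against 9818 ± 1072 CPM. The abundant miR-30a-5p was lower by a smaller step, at 58491 ± 7582 against 71001 ± 10457 CPM.

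By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 34 of the 269 miRNAs differed between the lines, 18 higher and 16 lower in the α1ACT line. The count was 19 in the other count table, where the names of a pair of vector columns may be exchanged (below). It was 18 when that pair was exchanged in the main table, so a drop of this size came with the exchange alone. With the pair exchanged in the other table instead, the count stayed within 1.5 times of 34. Without vector 6 h replicate 2 it was 16. At an unadjusted p under 0.05 there were 77, where chance gives 13.5. Most changes were small: the median absolute log2 fold change of the 34 was 0.27, and 4 reached 1 or more. Of the 34, 33 had 1 sign at all 4 times, which follows in part from calling them on the mean of these times. The log2 fold change was 1.91 for miR-181a-5p (SE 0.195, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.39e-07). It was 1.2 for miR-708-3p (SE 0.218), 1.16 for miR-708-5p (SE 0.244), 0.70 for miR-9a-5p (SE 0.124) and 0.47 for miR-34c-5p (SE 0.0877), with edgeR Benjamini-Hochberg adjusted p of 0.000391, 0.00228, 0.000349 and 0.000391 in that order. Also called higher were miR-499-5p (0.52), miR-760-3p (0.50), miR-129-5p (0.49) and the abundant miR-22-3p (0.18), with edgeR Benjamini-Hochberg adjusted p of 0.0490, 0.0451, 0.0490 and 0.0415. Among those that fell, the log2 fold change was -0.76 for miR-143-3p (SE 0.112), -0.48 for miR-10a-5p (SE 0.0770) and -0.26 for miR-30a-5p (SE 0.0469), with edgeR Benjamini-Hochberg adjusted p of 0.000139, 0.000161 and 0.000349. It was -0.42 for miR-15b-3p, -0.28 for miR-30c-5p, -0.27 for both miR-188-5p and miR-30c-2-3p, -0.25 for miR-152-5p and -0.16 for miR-27b-3p, all past the same threshold. The balance of higher and lower calls moved with the scaling, with 43 higher and 5 lower under upper-quartile factors and 36 higher and 5 lower under library totals, and 23 of the 34 called under each. The calls of miR-499-5p, miR-760-3p, miR-129-5p, miR-15b-3p, miR-188-5p, miR-152-5p and miR-27b-3p held in 19 or fewer of 37 alternative settings. A core of 14 miRNAs was called in both count tables and with a pair of vector columns exchanged or left out, among them miR-181a-5p, miR-708-3p, miR-708-5p, miR-34c-5p, miR-143-3p, miR-10a-5p, miR-30a-5p and miR-30c-5p.

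**Figure D1:**
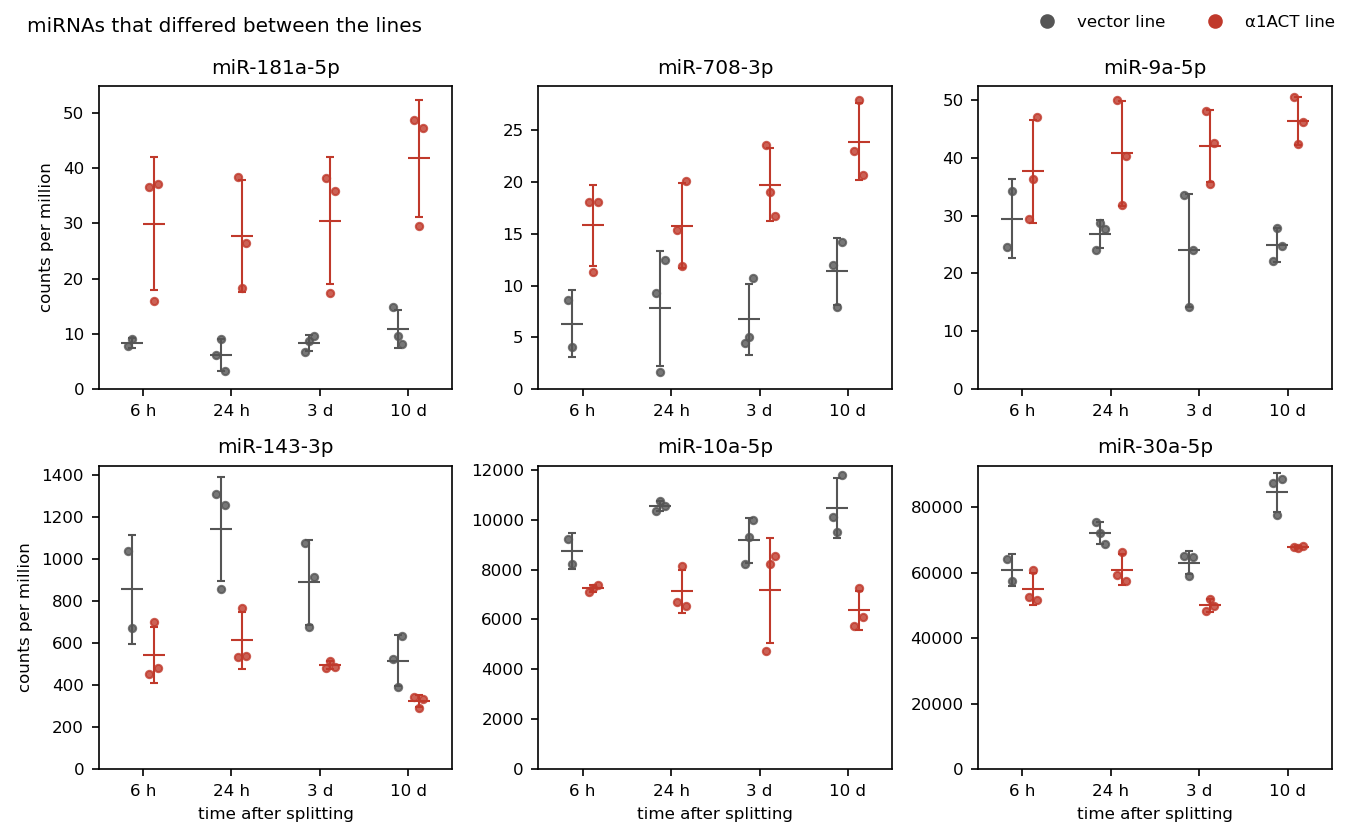
CPM of 6 miRNAs at the 4 times after splitting in the vector line (grey) and the α1ACT line (red); points are libraries, horizontal lines are means and bars are SDs. The mean of miR-181a-5p lay between 27.7 and 41.8 in the α1ACT line and between 6.20 and 10.9 in the vector line, while miR-143-3p, miR-10a-5p and miR-30a-5p had lower means in the α1ACT line at all 4 times.

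**Figure D2:**
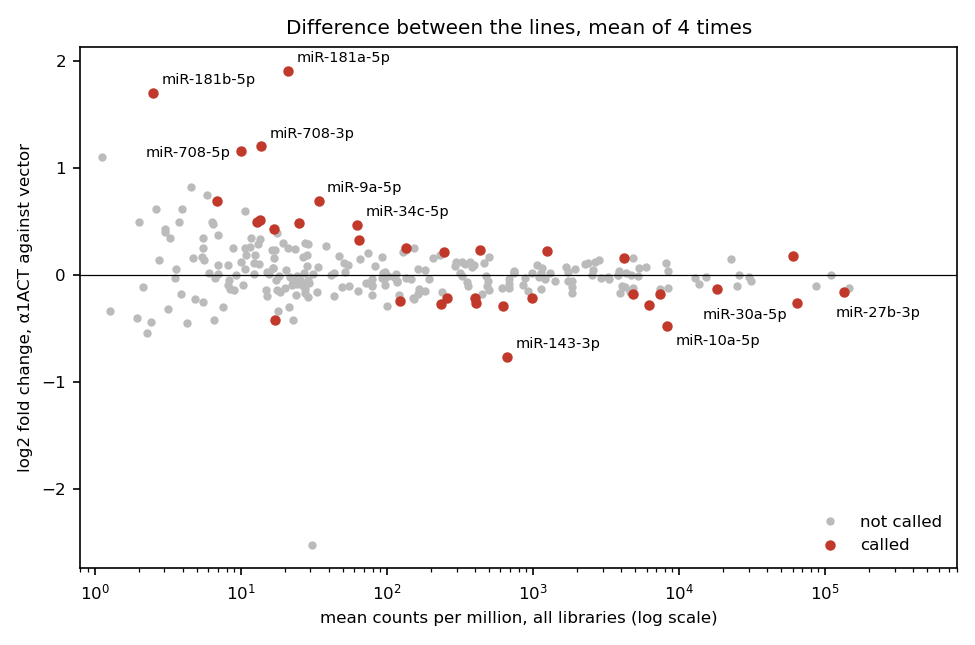
Log2 fold change of the α1ACT line against the vector line (mean of 4 times) for each of the 269 tested miRNAs, against its mean CPM on a log scale; red points passed the edgeR test and grey points did not. The 4 called miRNAs with a log2 fold change of 1 or more were miR-181a-5p, miR-181b-5p, miR-708-3p and miR-708-5p; the grey point near the bottom is let-7c-2-3p, an uncertain entry with counts in libraries where let-7a-1-3p had 0.

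Lists of miRNAs fixed before the data were examined showed where these differences fell. Within the miR-181 family, which acts in lymphocyte and neural development, 2 of 5 tested members rose (2 also when adjusted over the list alone): miR-181a-5p and the scarce miR-181b-5p (log2 fold change 1.71, mean 2.52 CPM). Hairpins of these 2 miRNAs lie side by side at 2 places in the genome. The other family members, miR-181c-5p (0.11), miR-181d-5p (0.05) and miR-181c-3p (-0.01), were abundant and not called. Mature sequences of this family are close to each other, so counts of its scarce members beside abundant ones are uncertain. Of 21 neuronal miRNAs, 4 rose (5 adjusted over the list alone) and none fell: miR-9a-5p, miR-138-5p (0.23), miR-129-5p and miR-344b-5p (0.43), and 18 had a positive fold change. Of 5 p53-induced miRNAs, 3 rose (4 adjusted over the list alone), namely miR-34c-5p, miR-34a-5p (0.33) and miR-192-5p (0.16), while miR-194-5p (0.16) and miR-107-3p (-0.04) were not called over all miRNAs. Of 9 members of the miR-30 family, 5 fell (6 adjusted over the list alone): miR-30a-5p, miR-30c-5p, miR-30c-2-3p, miR-30a-3p (-0.21) and miR-30d-5p (-0.13). The main table has no miR-30b entry. In the other count table miR-30b-5p (-0.085) and miR-30b-3p (-0.19) were not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.379 and 0.392). In the growth-promoting miR-17-92 and paralogous clusters 15 of 17 members had a negative fold change, but 1 fell (1 adjusted over the list alone), miR-25-3p (-0.18). In the miR-148, miR-152, miR-130 and miR-301 families 9 of 10 were negative and 1 fell (1 adjusted over the list alone), miR-152-5p. Of 4 mesenchymal and endothelial miRNAs 1 fell (1 adjusted over the list alone), miR-143-3p, while miR-126a-5p (-0.19), miR-126a-3p (-0.17) and miR-199a-3p (0.01) were not called.

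These 7 lists passed camera's competitive test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 17 lists. The miR-30 family led with a median log2 fold change of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.000270, and adjusted p = 0.0604 with an estimated correlation). The miR-181 family followed with a median of 0.11 and a mean of 0.75, set by 2 members (camera, Benjamini-Hochberg adjusted p = 0.00200, and adjusted p = 0.0604 with an estimated correlation), and then the neuronal list with a median of 0.17 (camera, Benjamini-Hochberg adjusted p = 0.0108, and adjusted p = 0.0604 with an estimated correlation). For the p53-induced list the median was 0.16 (camera, Benjamini-Hochberg adjusted p = 0.0194, and adjusted p = 0.130 with an estimated correlation). Medians were -0.18 for the mesenchymal list, -0.13 for the miR-148, miR-152, miR-130 and miR-301 families and -0.13 for the miR-17-92 clusters, with camera's Benjamini-Hochberg adjusted p of 0.0283, 0.0283 and 0.0330, and adjusted p = 0.161, 0.244 and 0.0849 with an estimated correlation. No list passed with an estimated correlation. All 7 passed fry, which does not set a list against the other miRNAs (largest Benjamini-Hochberg adjusted p = 0.0132). The signs of all 7 medians were kept under each of 3 other scalings, but the miR-148, miR-152, miR-130 and miR-301 families lost their call under library totals and upper-quartile factors (camera, Benjamini-Hochberg adjusted p = 0.0777 and 0.0851). Over 33 alternative settings these families kept their call in 24, the miR-17-92 clusters in 29, the mesenchymal list in 31 and each other list in 32. Under upper-quartile factors the median shrank to -0.07 for the miR-30 family and to -0.04 for the miR-17-92 clusters. It shrank to -0.04 for the miR-148, miR-152, miR-130 and miR-301 families and to -0.09 for the mesenchymal list. The medians of the lists that rose grew, to 0.20 (miR-181 family), 0.25 (p53-induced) and 0.26 (neuronal).

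The other 10 lists with 3 or more tested members did not pass camera's test. In the let-7 family (19 tested members, camera, Benjamini-Hochberg adjusted p = 0.866) let-7d-3p was called lower over all miRNAs (-0.29) and 0 members adjusted over the list alone. Its members let-7a-1-3p and let-7c-2-3p stayed uncertain, because every library had counts in 1 of these like-named 3p entries and 0 in the other. In the miR-15/16 family (11 members, camera, Benjamini-Hochberg adjusted p = 0.331) miR-15b-3p and miR-195-3p (-0.22) fell, 2 also adjusted over the list alone. No neuroendocrine miRNA was called over all miRNAs (8 members, camera, Benjamini-Hochberg adjusted p = 0.371), but 2 fell adjusted over the list alone, miR-375-3p (-0.12) and miR-183-5p (-0.17). The hypoxia and stress list (4 members, camera, Benjamini-Hochberg adjusted p = 0.358) likewise had 0 calls over all miRNAs and 2 adjusted over the list alone, miR-484 (-0.21) and miR-210-3p (-0.16). The miR-29 family (6 members, camera, Benjamini-Hochberg adjusted p = 0.663) and the miR-221, miR-222 and growth-factor list (6 members, 0.244) had 0 calls over all miRNAs and 0 adjusted over the list alone by edgeR's test. The growth-factor list did pass fry, with direction up (Benjamini-Hochberg adjusted p = 0.0173). In the epithelial list of the miR-200 family with miR-203 and miR-205 (4 members, camera, Benjamini-Hochberg adjusted p = 0.929) miR-203a-3p, which is outside that family, fell (-0.22, 1 also adjusted over the list alone). Its median (0.18) and mean (0.16) were positive while camera's direction was down. In the miR-23/27/24 clusters (10 members, camera, Benjamini-Hochberg adjusted p = 0.894) miR-27b-3p fell and miR-24-2-5p (0.19) was called as well when adjusted over the list alone. The median there (0.01) was positive while the mean (-0.02) and camera's direction were negative. The group of miR-99, miR-100, miR-125 and miR-10 (13 members, camera, Benjamini-Hochberg adjusted p = 0.209) had 1 call, miR-10a-5p, also adjusted over the list alone. The glial list (4 members, camera, Benjamini-Hochberg adjusted p = 0.575) had 1 call, miR-338-3p (0.23), also adjusted over the list alone. Lists with under 3 tested members were not tested as sets. The Dlk1-Dio3 list had 2 tested members, miR-345-3p and miR-345-5p, and the inflammation-linked list 2, miR-147 and miR-146b-5p, none of them called. Whether miR-345 lies in the Dlk1-Dio3 cluster itself was not checked, so these values are not a reading of that cluster. The muscle list had 1, miR-499-5p (called, above), and the blood-cell list 1, miR-142-5p (0.40, not called). The X-linked cluster and the liver miRNA had 0 tested members.

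At single times the excess of miR-181a-5p in the α1ACT line stood out. It was at 27.7 ± 10.1 CPM against 6.20 ± 2.92 at 24 h, at 30.5 ± 11.5 against 8.38 ± 1.5 at 3 d and at 41.8 ± 10.6 against 10.9 ± 3.45 at 10 d (SD, n = 3 each). At 10 d miR-9a-5p was also higher, at 46.4 ± 4.14 against 24.9 ± 2.90 CPM, while miR-10a-5p was lower (6368 ± 788 against 10471 ± 1197 CPM) and so was miR-100-5p (97.4 ± 8.36 against 195 ± 62.9 CPM), which is encoded beside a let-7 hairpin.

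The log2 fold change of miR-181a-5p was 2.11 at 24 h (SE 0.384), 1.78 at 3 d (SE 0.385) and 1.93 at 10 d (SE 0.351), with edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.00283, 0.0282 and 0.00282. At 10 d it was 0.90 for miR-9a-5p (SE 0.233), -1.0 for miR-100-5p (SE 0.214) and -0.72 for miR-10a-5p (SE 0.150), with edgeR Benjamini-Hochberg adjusted p of 0.0415, 0.00927 and 0.00899. These made 1 call at 24 h, 1 at 3 d and 4 at 10 d, with 28, 24 and 40 miRNAs at an unadjusted p under 0.05. At 6 h edgeR's quasi-likelihood test called 0 miRNAs, with 30 at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma-voom. It called 7 there without α1ACT 6 h replicate 2, and 2 when the 2 groups were fitted alone. There miR-181a-5p had a log2 fold change of 1.83 (SE 0.433, edgeR Benjamini-Hochberg adjusted p = 0.0744). No miRNA was therefore called at all 4 times by edgeR (0, limma-voom 0, DESeq2 1), and 31 of the 34 miRNAs of the mean comparison were called at no single time. With a replicate block edgeR called 1 miRNA at all 4 times, and also 1 with no low-count filter. Counts of calls at single times moved with single libraries: the call at 3 d was lost in the other count table and when any 1 of 7 libraries was left out, and the 4 calls at 10 d became 0 without vector replicate 3 of that time. The log2 fold change of miR-181a-5p kept its sign in all 38 settings at 24 h, 3 d and 10 d, and its call held in 36, 24 and 37 of them. It ranged over 1.79–2.50 at 24 h and 1.53–2.06 at 3 d.

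Whether the difference between the lines changed with time was asked with an interaction test. The smallest p belonged to miR-100-5p, for which the log2 fold change of α1ACT against vector was 0.54 at 6 h, -0.49 at 24 h, 0.24 at 3 d and -1.0 at 10 d. For miR-99b-5p it was 0.67 at 6 h and -0.66 at 10 d, for miR-125b-5p 0.78 and -0.42, for miR-125a-5p 0.74 and -0.43, and for miR-210-5p 0.31 and 0.38. The values of miR-210-5p at 6 h and 10 d were alike, so its low p rested on 24 h or 3 d. By edgeR's quasi-likelihood F test 0 miRNAs passed, with 10 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom. The edgeR Benjamini-Hochberg adjusted p was 0.0716 for miR-100-5p and 0.248 for miR-99b-5p. The count was also 2 in the other count table, and it was 4 without α1ACT 6 h replicate 2.

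In the α1ACT line, the time after splitting went with large decreases of the 5p arms of miR-99b, miR-100, miR-125a and miR-125b, which are linked to differentiation. From 6 h to 10 d miR-125a-5p went from 13204 ± 5118 to 4104 ± 255 CPM, miR-99b-5p from 17437 ± 3997 to 6256 ± 593 CPM, miR-125b-5p from 5663 ± 2036 to 1817 ± 145 CPM and miR-100-5p from 327 ± 56.9 to 97.4 ± 8.36 CPM (SD, n = 3 each). The means of miR-99b-5p, miR-125a-5p and miR-100-5p were lower still at 3 d, for miR-100-5p at 62.4 ± 13.8 CPM (SD, n = 3). Among miRNAs with a mean of at least 10 CPM the largest fall was that of miR-501-3p, from 227 ± 52.0 to 38.6 ± 5.24 CPM, whose hairpin lies within the gene Clcn5. The scarce miR-23b-5p (mean 4.86 CPM), picked after its values were seen, fell by more (log2 fold change -5.51, SE 0.747, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.94e-06). Among those that rose were miR-338-3p, which is encoded within Aatk and is known from glia and neurons (405 ± 34.7 to 656 ± 82.6 CPM), miR-598-3p, miR-344a-3p, miR-1843b-5p and the hypoxia-linked miR-210-5p.

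By edgeR's quasi-likelihood test 73 miRNAs differed between 10 d and 6 h in the α1ACT line, 30 higher and 43 lower, and 114 differed among its 4 times. The log2 fold change was -2.54 for miR-501-3p (SE 0.307), -1.75 for miR-100-5p (SE 0.217), -1.69 for miR-125a-5p (SE 0.209), -1.64 for miR-125b-5p (SE 0.203) and -1.48 for miR-99b-5p (SE 0.209), with edgeR Benjamini-Hochberg adjusted p of 1.94e-06, 1.94e-06, 2.38e-06, 2.38e-06 and 1.28e-05. It was 0.74 for miR-1843b-5p, 0.71 for miR-344a-3p, 0.70 for miR-338-3p, 0.63 for miR-598-3p and 0.60 for miR-210-5p, with edgeR Benjamini-Hochberg adjusted p of 0.0451, 0.0169, 0.000270, 0.00104 and 0.0256. In the group of miR-99, miR-100, miR-125 and miR-10, 5 of 13 members fell (5 adjusted over the list alone), the fifth being miR-99b-3p (-0.36). Not called were miR-125a-3p (-0.17), miR-125b-1-3p (-0.25), miR-125b-2-3p (0.38), miR-196a-5p (0.56), miR-10a-5p (-0.19) and miR-10b-5p (-0.08), among others. The group had a median of -0.19 and a mean of -0.51, and it was the 1 list past camera's test (Benjamini-Hochberg adjusted p = 0.0128, and adjusted p = 0.568 with an estimated correlation). All 4 members of the hypoxia and stress list were called but in both directions (2 up and 2 down, also adjusted over the list alone): miR-210-3p (0.56) and miR-210-5p rose, and miR-484 (-1.02) and miR-320-3p (-0.49) fell. Of the p53-induced list 3 of 5 rose (3 adjusted over the list alone), namely miR-192-5p (0.32), miR-194-5p (0.34) and miR-107-3p (0.37), and of the miR-181 family 2 of 5 rose (2 adjusted over the list alone), miR-181c-5p (0.37) and miR-181d-5p (0.36). With upper-quartile factors 16 were higher and 48 lower.

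**Figure D3:**
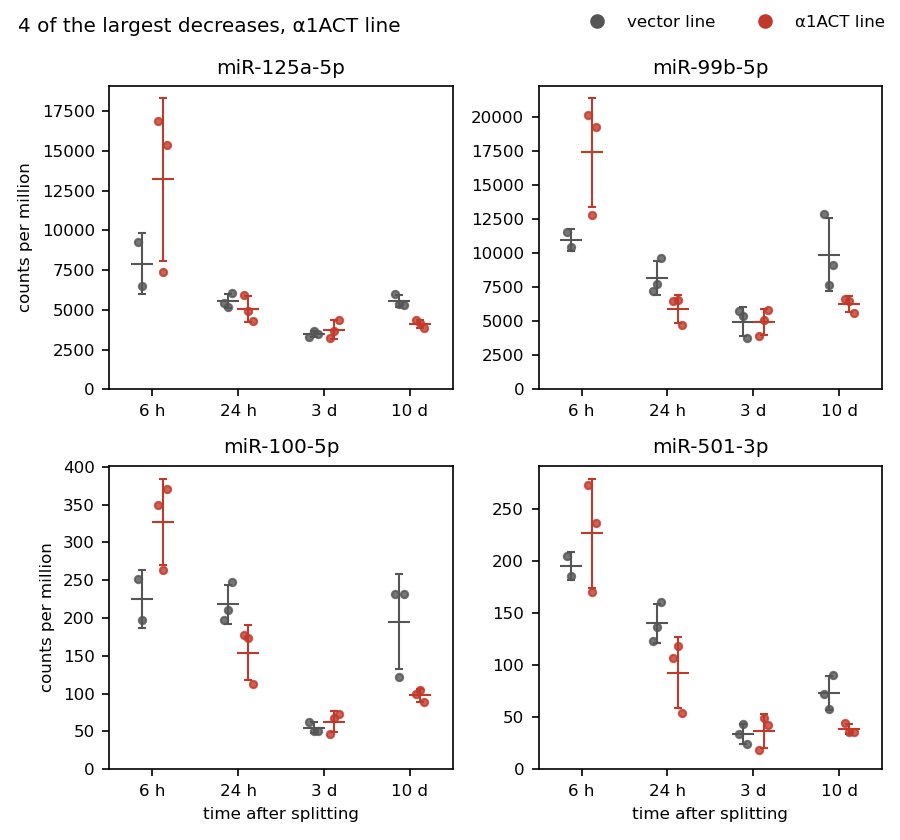
CPM of miR-125a-5p, miR-99b-5p, miR-100-5p and miR-501-3p at the 4 times after splitting in the vector line (grey) and the α1ACT line (red); points are libraries, horizontal lines are means and bars are SDs. Means in the α1ACT line dropped between 6 h and 10 d, for miR-125a-5p from 13204 to 4104.

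In the vector line, as a control for time in culture, miR-501-3p fell as well, together with miR-27a-5p, let-7d-3p, miR-503-3p and miR-484. At 6 h miR-501-3p was at 195 ± 13.2 CPM (SD, n = 2) and at 10 d at 73.3 ± 16.3 CPM (SD, n = 3), and miR-484 went from 199 ± 37.8 to 95.6 ± 3.83 CPM. Among called miRNAs those that rose most were miR-338-3p (344 ± 42.4 to 558 ± 32.5 CPM), miR-181c-5p, miR-23a-3p, miR-153-3p and miR-29b-3p. The 4 arms of miR-99b, miR-100 and miR-125 named above had log2 fold changes of -0.51 (miR-125a-5p), -0.44 (miR-125b-5p), -0.20 (miR-100-5p) and -0.15 (miR-99b-5p) between 10 d and 6 h and were not called there. All 4 were called among the 4 times of the vector line (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00299, 0.0112, 3.16e-06 and 0.00189 in that order). Their means were lowest at 3 d, for miR-100-5p at 54.4 ± 7.25 CPM (SD, n = 3). The interaction test on all libraries called none of them.

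By edgeR's quasi-likelihood test 32 miRNAs differed between 10 d and 6 h in the vector line, 14 higher and 18 lower, and 99 differed among its 4 times. The log2 fold change was -1.41 for miR-501-3p (SE 0.317), -1.30 for miR-27a-5p (SE 0.324), -1.14 for let-7d-3p (SE 0.193), -1.08 for miR-503-3p (SE 0.306) and -1.06 for miR-484 (SE 0.159), with edgeR Benjamini-Hochberg adjusted p of 0.00405, 0.00656, 0.000205, 0.0184 and 2.05e-05. It was 0.70 for miR-338-3p, 0.58 for miR-181c-5p, 0.56 for miR-23a-3p, 0.54 for miR-153-3p and 0.51 for miR-29b-3p, with edgeR Benjamini-Hochberg adjusted p of 0.00196, 0.000919, 0.00955, 0.00989 and 0.0315. No list passed camera's test (smallest Benjamini-Hochberg adjusted p 0.209). Of the 32 miRNAs, 25 were called in the α1ACT line too, all 25 in the same direction, where independent lists would share 8.68 (Fisher's exact test, two-sided, p = 1.56e-10; miRNAs are not independent of each other). These included miR-484 (-1.06 in the vector line and -1.02 in the α1ACT line), miR-92a-3p (-0.90 and -1.0) and miR-423-3p (-1.01 and -0.93). This comparison rests on how a pair of libraries is named. In the other count table the columns named vector 6 h replicate 2 and vector 10 d replicate 2 hold each other's counts, and edgeR called 0 miRNAs there (8 at an unadjusted p under 0.05), while DESeq2 and limma-voom, run on the sRNAbench table alone, called 38 and 37. Omitting both libraries leaves 1 vector library at 6 h, whose spread then has to be taken from the other groups. Upper-quartile factors gave 43 higher and 17 lower and library totals 5 higher and 27 lower.

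**Figure D4:**
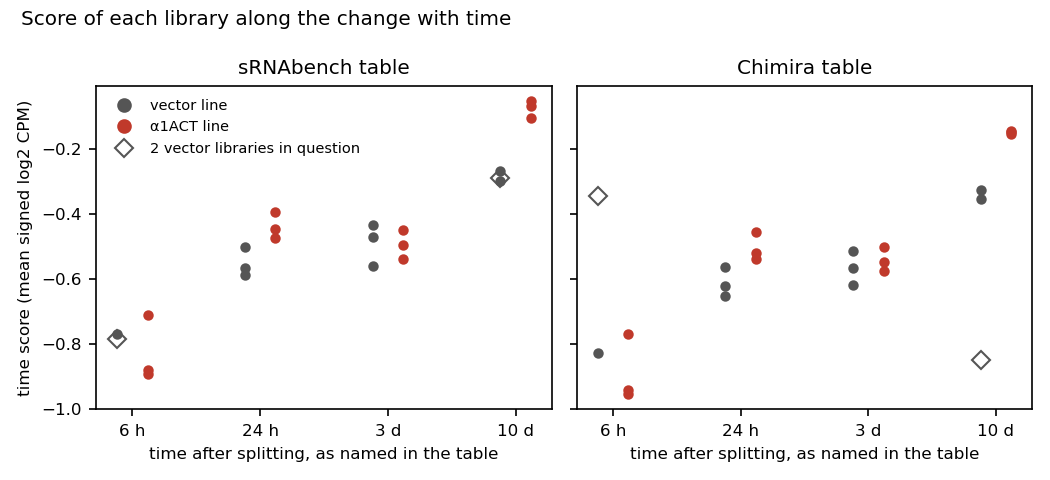
Score of each library (the mean log2 CPM of 73 miRNAs called between 10 d and 6 h in the α1ACT line, each signed by its direction there) at the time its column names give, in the sRNAbench table and in the Chimira table; red points are α1ACT libraries, by which the miRNAs were chosen, grey points are vector libraries and diamonds mark vector 6 h replicate 2 and vector 10 d replicate 2. In the sRNAbench table the diamonds lie with the other libraries of their named times, and in the Chimira table each lies with the libraries of the other time.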

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

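The settings with the pair of vector columns exchanged or left out, with the shallow library left out, with let-7a-1-3p and let-7c-2-3p summed, and the list tests with DESeq2 size factors or upper-quartile factors were chosen after the data had been seen. Counts of calls stayed within 1.5 times of the reported count in 133 of 188 values under alternatives and in 277 of 322 values with a library left out. Named miRNAs and lists kept their call in 572 of 698 values and lost it with the same sign in 121, and with a library left out they kept it in 1020 of 1196 and lost it in 176. In the mean comparison miR-181a-5p, both arms of miR-708, miR-34c-5p, miR-143-3p, miR-10a-5p, miR-30a-5p, miR-30c-5p and miR-30c-2-3p kept their calls in 37 of 37 settings, and miR-9a-5p in 35 of the 35 in which it was tested. In the vector line 5 values reversed between 10 d and 6 h: with the Chimira table miR-338-3p (-0.0767), miR-181c-5p (-0.00854) and miR-153-3p (-0.0766), and with the columns exchanged in the sRNAbench table miR-338-3p (-0.0103) and miR-484 (0.00705). These 2 settings give both libraries the other time's name than the sRNAbench table does. On the time score the column named vector 6 h replicate 2 lay at -0.0371 in the sRNAbench table, which argues against an exchange there, so these settings mix the times. For the other shifts below the cause was not tested. At the depths of these libraries simulated 1.5-fold changes were called in 88.6% for the mean comparison, 51.8% for the lines at 10 d and 50.4% for 10 d against 6 h in the α1ACT line. Depth apart from the number of libraries was not tested.

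With the columns exchanged in the sRNAbench table the counts became 18 (mean of the 4 times), 0 (vector line, 10 d against 6 h), 46 (vector line, 4 times) and 2 (interaction). With the Chimira table they were 19 (mean), 0 (vector line, 10 d against 6 h), 56 (vector line, 4 times), 2 (interaction), 11 (10 d) and 0 (3 d), with 17 of the 19 among the 34. With its columns exchanged they were 2 (24 h) and 0 (3 d). With both libraries left out they were 16 (mean), 11 (vector line, 10 d against 6 h), 7 (10 d), 2 (24 h), 2 (3 d) and 1 (interaction). Without the shallow library too they were 14, 10, 7, 2 (24 h) and 1 (interaction). Fits without these libraries leave 1 vector library at 6 h, which is assumed to vary like the others. DESeq2 gave 3 (6 h), 3 (24 h), 6 (3 d), 10 (10 d), 1 (all 4 times) and 2 (interaction), and limma-voom 0 (24 h) and 0 (3 d). DESeq2 size factors in edgeR gave 3 (24 h), and library totals 2 (24 h). Upper-quartile factors gave 60 (vector line, 10 d against 6 h), 2 (6 h), 2 (24 h), 0 (3 d) and 1 (interaction). These scalings moved the median of all miRNAs by more than 0.1 at 6 h (0.196, upper quartile), at 24 h (0.11 and, for totals, 0.109), at 10 d (0.114, totals) and in the vector line between 10 d and 6 h (0.167 and -0.108). With a mean CPM of at least 10 there were 3 (24 h), and with no filter 1 (6 h) and 1 (all 4 times). With the let-7 pair summed there were 2 (24 h), 4 (3 d) and 1 (interaction). Fits of the 2 groups alone gave 2 (6 h), 3 (24 h), 2 (3 d) and 11 (10 d). Camera with an estimated correlation called 0 lists in the mean comparison and 0 in the α1ACT line over time, while fry called 7 there and 3 in the vector line. With 6 lists, the miR-148, miR-152, miR-130 and miR-301 families lost their call under upper-quartile factors and under library totals (camera, Benjamini-Hochberg adjusted p = 0.0851 and 0.0777).

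With the replicate number as a replicate block, the counts were 1 (6 h), 3 (24 h), 1 (all 4 times) and 38 (mean), and no other count of calls moved by over 1.5 times. The numbers were not taken to pair the samples, as 36 of 77 pairs of same-numbered libraries had deviations correlated at r over 0.1. The median r was 0.0787 for the same number and -0.0434 for other numbers. Values for the same number ran from -0.796 to 0.887, so a tie by number is not excluded. In the α1ACT line replicate 2 did stand apart at all 4 times (below). If same-numbered libraries share a culture across times, the libraries are not independent, and p-values of the mean comparison would be too small.

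With single libraries left out, counts ranged over 16–40 (mean), 0–7 (6 h), 0–2 (24 h), 0–5 (3 d), 0–6 (10 d), 0–1 (all 4 times), 0–4 (interaction), 16–41 (vector line, 10 d against 6 h), 50–79 (α1ACT line, 10 d against 6 h), 84–105 (vector line, 4 times) and 94–131 (α1ACT line, 4 times). For lists they ranged over 5–7 (mean), 0–0 (vector line) and 1–1 (α1ACT line). The mean comparison fell to 16 without vector 6 h replicate 2, to 20 without α1ACT 3 d replicate 3, to 21 without α1ACT 6 h replicate 3 or α1ACT 24 h replicate 1, and to 22 without α1ACT 6 h replicate 1, vector 24 h replicate 2 or vector 10 d replicate 2. The vector line between 10 d and 6 h fell to 16 without vector 6 h replicate 2, whose omission leaves 1 library at 6 h that is assumed to vary like the others. At 10 d the count was 0 without vector replicate 3, 1 without α1ACT replicate 1 or 3, and 2 without vector replicate 1 of that time. At 3 d it was 0 without vector 24 h replicate 1, vector 3 d replicate 3, α1ACT 3 d replicate 1 or 3, vector 10 d replicate 2 or α1ACT 10 d replicate 1 or 3, 2 without α1ACT 24 h replicate 3, 4 without vector 3 d replicate 2, and 5 without vector 6 h replicate 1 or 2 or vector 24 h replicate 2. At 24 h it was 0 without vector 24 h replicate 1 and 2 without any of 10 others. At 6 h it was 7 without α1ACT 6 h replicate 2 and 1 without α1ACT 24 h or 3 d replicate 2. The interaction gave 4 without α1ACT 6 h replicate 2 and 1 without α1ACT 24 h replicate 3, α1ACT 3 d replicate 1 or vector 10 d replicate 2.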

Other observations

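The tests of counting tools, of replicate 2, of 1 pair per cluster and of hairpin arms were chosen only after the result was seen.

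Among entries counted by Chimira but not tested in the sRNAbench table, 2 differed between the lines in the mean comparison: miR-335 (log2 fold change -0.30, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0119) and miR-320-5p (-0.95, edgeR Benjamini-Hochberg adjusted p = 0.0316) fell in the α1ACT line.

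Between 10 d and 6 h the vector line had 32 calls in the sRNAbench table and 0 in the Chimira table. The columns named vector 6 h replicate 2 and vector 10 d replicate 2 hold each other's counts in the tables, and exchanging them in the Chimira table gave 43 calls. A loss of all calls through the counting tool alone is argued against by the α1ACT line, which holds neither library. There were 71 calls there by Chimira and 73 by sRNAbench, 60 of them in both. The log2 fold changes of that line had r = 0.727 between the tables across miRNAs, so the tools differed for some entries. For 154 miRNAs with at least 100 counts they were close, with a median absolute log2 ratio of 0.0233 or less in each α1ACT library. Which entries lowered r was not tested. On a scale of time score from 0 (vector 6 h replicate 1) to 1 (mean of vector 10 d replicates 1 and 3), the column named vector 6 h replicate 2 lay at -0.0371 in the sRNAbench table, against an exchange there, and at 0.991 in the Chimira table, so a candidate explanation is an exchange of names in the Chimira table. No biological explanation was tested.

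The fall of miR-143-3p in the α1ACT line might reflect fewer mesenchymal cells or less of their RNA, from serum or other cells, or a change within PC12 cells. The other 3 tested mesenchymal and endothelial miRNAs had a median log2 fold change of -0.168, short of the -0.382 set beforehand as a match. To argue against another cell type, it had to lie above -0.191 by more than its SE. The mean of the 3 was -0.117 with an SE of 0.0622, but the bounds had been set for the median, whose own SE was not estimated from 3 values. Among the 3, miR-126a-5p and miR-126a-3p come from the same hairpin, and the median is the value of miR-126a-3p. The remaining member, miR-199a-3p, did not fall, with 358 counts over the vector libraries and 385 over the α1ACT libraries. The median is thus a poor measure of mesenchymal cells, and the explanations given cannot be told apart for miR-143-3p. Its cluster partner miR-145-5p, abundant where smooth muscle cells are, had 0 counts over all vector libraries and 2 over all α1ACT libraries, against 23013 and 14784 for miR-143-3p. A shallow or exchanged vector library is argued against, because without those 3 libraries the log2 fold change was -0.841 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.54e-05). An effect of α1ACT in PC12 cells and a difference between clones stay open as untested.

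In the α1ACT line replicate 2 was nearest to the vector line at 4 of 4 times, by a score of 30 miRNAs called in the mean comparison other than miR-181a-5p, miR-143-3p and miR-708. The score was built on the same libraries after the pattern had been seen, so it describes the pattern and is no fresh test of it. Replicate 2 also had the lowest miR-181a-5p at each time, at 16, 18.3, 17.3 and 29.6 CPM, where the others ran from 26.4 to 48.7. A shared property of the libraries numbered 2, such as a culture with less α1ACT or a shared preparation, is a candidate explanation, which these counts do not separate since the labels name neither.

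One hypothesis was that neighbouring hairpins share transcription units and so differ together between the lines. Over 210 pairs of tested miRNAs with hairpins within 10 kb, the median absolute difference in log2 fold change was 0.136, against 0.184 (0.157 to 0.213 but for the outer tails) for random partners of like abundance (one-sided permutation p = 1e-04, the smallest that 10000 pairings can give). Many of these pairs share a member and so are not independent of each other, and strand was ignored. With 1 pair from each of 24 clusters the median absolute difference was 0.088 against 0.149 (one-sided permutation p = 0.0099). The miR-181a and miR-181b hairpins, and those of miR-182, miR-183 and miR-96, are such neighbours, and the result may reflect shared transcription, though similar sequences within some clusters could share reads.

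A second hypothesis was a shift between hairpin arms with time in culture. Over 76 hairpin names with both arms tested, the minor arm's log2 fold change between 10 d and 6 h differed from the major arm's by a mean of -0.202 in the vector line (two-sided permutation p = 0.0042) and -0.282 in the α1ACT line (p = 0.0041, both adjusted p = 0.0042, 100000 permutations). The minor arm was lower in 43 and 46 of 76, and the medians were -0.0761 and -0.0964, nearer to 0 than the means. A loss of minor arms that spans most hairpins is therefore not shown, and how few hairpins carry the means was not tested.

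Other splits of the libraries into groups of the same sizes were counted. For the mean comparison 1 of 100 splits, the real one, gave as many as 34 calls and the highest other gave 5. A chance assignment of independent libraries within each time is thus excluded at a share under 0.05. For time in the α1ACT line 1 of 100 gave as many as 114, with a highest other of 77. A chance assignment of independent libraries to times is excluded there at the same share. The splits treat libraries as exchangeable, so they cannot exclude a chance difference between clones or cultures. For the interaction 100 of 100 splits gave at least the real 0, and the highest other gave 4. With a real count of 0 no other outcome was possible, so this says nothing about chance. For the lines at 24 h, 3 d and 10 d, and for 10 d against 6 h in the α1ACT line, 10 splits are too few for a share under 0.05: 1 of 10 gave as many in each, with real values of 1, 1, 4 and 73 and highest others of 0, 0, 0 and 3.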
